A study of Mus musculus with 60 samples.

How the data were processed

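The series holds Affymetrix Mouse430_2 arrays of 60 tissue samples. They are 25 lymphomas of Eµ-myc transgenic mice with early onset (32 to 76 days of age), 25 lymphomas of the same genotype with late onset (253 to 649 days) and 10 normal tissues of wild-type mice. Groups were taken from the sample labels. The normal tissues are 6 lymph nodes of young mice (38 to 73 days), 3 lymph nodes of old mice and 1 spleen of an old mouse (304 to 438 days for the old tissues together). Per the labels' protocols, total RNA came from snap-frozen tissue, and biotin-labelled cRNA was made from 6 µg of it. The labels name a single tumour or tissue per array but do not say which arrays share a mouse, a litter, a batch or a day, so p-values measure the spread between these samples. The highest correlation between any 2 arrays was 0.968 and the lowest was 0.819, and no pair held identical values.

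The deposited values are intensities on a linear scale, made by the authors with MAS5 per the submitters' processing notes, which give no version. Each array had been scaled to a common level: the mean after leaving out the lowest and highest 2% of probe sets lay between 499.84 and 499.89 on every array. Detection calls and any filter applied before deposit are not given in the sources used here. Of 45101 probe sets, 34958 name 1 gene in the platform annotation, 932 name several and 9211 name none. Of those naming 1 gene, 34754 were found in the RefSeq gene table of assembly GRCm38.p6, used for names only, by their gene identifier. No gene was named from a probe set with several genes.

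All tests used log2(intensity + 15.7), where the pseudocount is the median of the whole table (157) divided by 10. A log2 change on this scale understates the change of dim genes. Probe sets above their own array's median on at least 10 of the 60 arrays were kept, and 64 control probe sets were left out, which left 27094 probe sets and 12635 genes. The arrays were not rescaled again. Each comparison was fitted with limma 3.58.1 (R 4.3.3; lmFit and eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment at a threshold of 0.05. A gene was represented by the probe set naming it alone with the highest mean over all arrays. The precision is limited by the number of arrays. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

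The comparisons were early against late lymphoma, each of them against all 10 normal tissues, old against young normal tissue, the difference between the onset contrast and the age contrast of normal tissue (an interaction over all 60 samples), and the slope on log2 age of onset within each lymphoma group. The spread within a lymphoma group was the Euclidean distance of each array to its group mean over the kept probe sets, compared by a permutation test with 1e+05 resamples. RNA quality was read from the log2 ratio of the 3-prime to the 5-prime control probe set of Gapdh and of beta-actin, from the hybridisation and Bacillus controls and from each array's median and 10th percentile, with the same permutation test and Benjamini-Hochberg adjustment.

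The lists, 33 in number, were fixed before the data were examined. They held 443 entries, of which 392 matched a probe set naming 1 gene. They cover B lineage, pro-B and pre-B, mature B, germinal centre, plasma cell, immunoglobulin, T cell, NK and cytotoxic, macrophage and monocyte, neutrophil, erythroid, platelet, stroma and endothelium, adipocyte, mitotic cell cycle, E2F targets and DNA replication, ribosome biogenesis, Myc metabolic targets, ribosomal proteins, p53 targets, the Arf, p53 and Bcl2 family, NF-kB targets, interferon response, MHC class II, MHC class I, Ras and ERK feedback, immediate early and heat shock, Wnt and beta-catenin targets, JAK-STAT feedback, glycolysis and hypoxia, oxidative phosphorylation, DNA repair and checkpoint, and sex-linked genes. List shifts were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the 32 lists with at least 3 measured genes; the erythroid list had 0 measured genes after the filter. List tests were planned for the 3 main comparisons, and those in normal tissue by age and in the interaction were added. A count "adjusted over the list alone" uses only the list's own members for the adjustment.

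The rule for named genes was fixed before the data were examined. It takes the 10 largest rises and 10 largest falls past the threshold in each of the 3 main comparisons, among genes whose higher group mean lies above the table median. It adds up to 4 members of each list, always Myc, Cdkn2a, Trp53, Mdm2, Bcl2, Bcl6, Ighm and 1 further gene that is not reported here, and up to 5 genes each way in the other fits. Trp53 is not analysed here, since no probe set naming it alone was used. Alternatives tried were a pseudocount 4 times larger or 10 times smaller, no filter or a filter of 30 arrays, quantile normalization, centring on the median, both RNA ratios as covariates, array weights, a single fit of all samples, a 2-fold minimum, a rank-sum test, cell type lists as covariates, 1 probe set per gene, the mean of all probe sets of a gene, probe sets open to cross-hybridisation left out, age in days, subsets of the normal tissues, arrays left out in turn and an estimated inter-gene correlation.

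The limma step was tested on simulated data with 100 probe sets changed at each of 2 sizes among the 27094. At a log2 change of 1 it recovered 95% of them for early against late lymphoma, 89% for early lymphoma against normal, 80% for late lymphoma against normal and 77% for old against young normal tissue. At a log2 change of 2 the shares were 100%, 100%, 98% and 95%.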

Results

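The data are expression profiles of lymphomas that arose in Eµ-myc mice, which carry Myc under the immunoglobulin heavy chain enhancer and develop B cell tumours, and of normal lymphoid tissue of wild-type mice. The samples are 25 lymphomas of early onset (mean age 62.6 ± 11.0 days, SD) and 25 of late onset (391.5 ± 101.8 days), beside 10 normal tissues. The median intensity per array was 148 ± 19.5 in early lymphomas, 155 ± 17.9 in late lymphomas and 190 ± 4.8 in normal tissue (SD). The series title and design set early against late tumours. Below, a value after ± is an SD beside a level and a standard error beside a log2 change, and p-values are limma's after Benjamini-Hochberg adjustment unless another test is named.

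Myc was measured first, since the transgene checks the labels. Its intensity was 13672 ± 2749.5 in early lymphomas (n = 25), 12383 ± 3091.9 in late lymphomas (n = 25) and 1177.3 ± 249.5 in normal tissue (n = 10). All 25 early and all 25 late lymphomas lay above the highest normal tissue, at 1606.3. Against normal tissue Myc rose by 3.52 ± 0.11 on the log2 scale in early lymphomas (adjusted p = 7.2e-26) and by 3.36 ± 0.14 in late lymphomas (adjusted p = 3.9e-20). Between late and early lymphomas the log2 change was -0.16 ± 0.10 (adjusted p = 0.22), which did not pass the threshold.

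**Figure D1:**
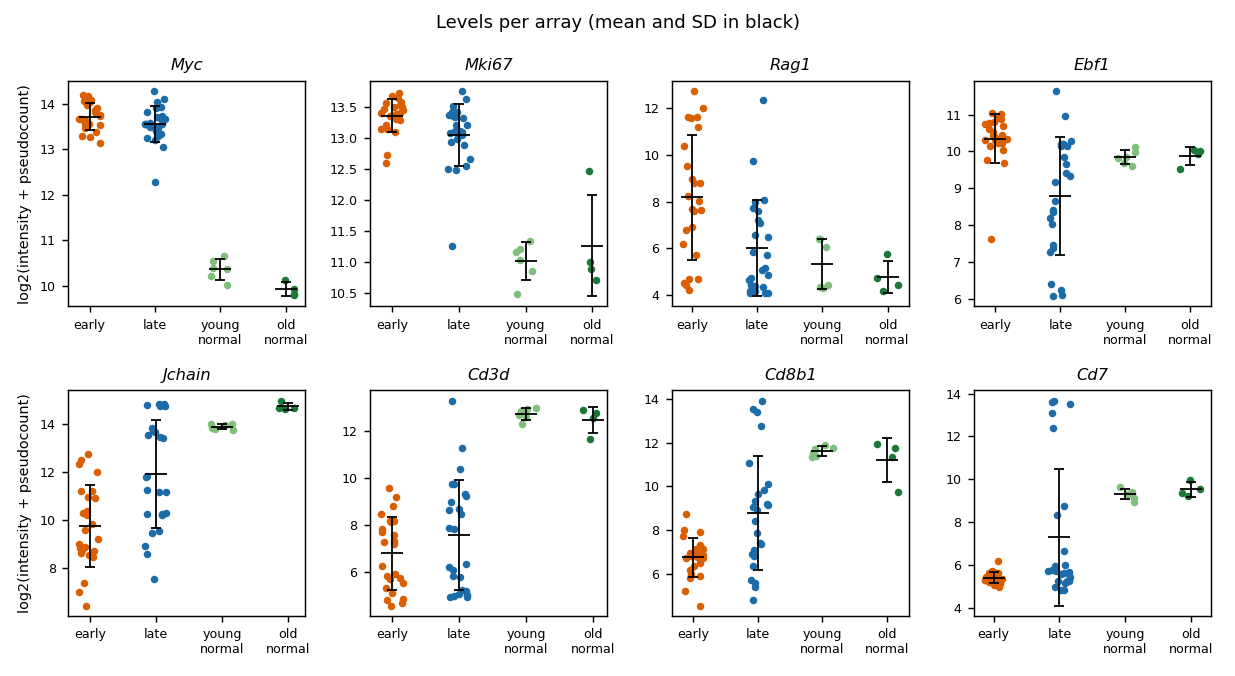
Levels of 8 genes on each array, as log2(intensity + pseudocount), for early lymphomas, late lymphomas, young normal tissue and old normal tissue; points are arrays, black marks are means and bars are SD. Myc lies above all normal tissues in all 50 lymphomas, while Jchain, Cd8b1 and Cd7 spread more widely in late than in early lymphomas.

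Early lymphomas differed from normal tissue in genes of proliferation, growth and the immune compartment. All 19 measured genes of the mitotic list were higher in early lymphomas, with a median log2 change of 2.50. Ube2c, which helps to degrade mitotic cyclins, rose by 3.09 ± 0.15, Cdk1, the mitotic kinase, by 3.01 ± 0.11 and Bub1, of the spindle checkpoint, by 2.93 ± 0.11. All 21 E2F targets were higher (median 1.95, with Cdc6 2.91 ± 0.16, Gins1 2.87 ± 0.11). So were 10 of 11 DNA repair and checkpoint genes (median 1.54, with Exo1 2.61 ± 0.10, Chek1 2.41 ± 0.08). All 18 ribosome biogenesis genes (median 1.86, with Nolc1 2.68 ± 0.11) rose, and all 15 Myc metabolic targets (median 1.97, with Shmt1, of one-carbon metabolism, 3.36 ± 0.11) did. Adjusted over the list alone the counts were the same in these 5 lists. In the list test the adjusted p was 2.4e-15, 3.5e-14, 1.8e-07, 5.4e-15 and 3.3e-12 in this order of lists. The calls held with an estimated correlation (adjusted p = 0.044, 0.033, 0.033, 0.030 and 0.022).

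Oxidative phosphorylation genes rose in 14 of 15 cases by less (median 0.85, with list adjusted p = 4.9e-07, and adjusted p = 0.11 with an estimated correlation). Of 9 measured ribosomal protein genes 5 rose (median 0.20), and the list was not called (adjusted p = 0.12). The 10 largest rises were Bcat1, which starts the breakdown of branched-chain amino acids (4.56 ± 0.11), Ptgr1 (3.97 ± 0.31), the centromere gene Cenpi (3.89 ± 0.14), Myc, Gm10451 (3.51 ± 0.16), Cpn1 (3.41 ± 0.76), Shmt1, the meiotic recombination gene Mnd1 (3.36 ± 0.24), Cdca7 (3.34 ± 0.14) and Zfp428 (3.25 ± 0.20). All 25 early lymphomas lay above every normal tissue for each of them except Cpn1, where 19 did.

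Genes of other immune and tissue cells were lower in early lymphomas. T cell markers fell in 14 of 15 cases, with a median change of -3.49. Cd3d of the T cell receptor complex fell by 5.86 ± 0.47, Cd8b1 fell by 4.71 ± 0.29 and Cd3e fell by 4.62 ± 0.29. All 25 early lymphomas lay below every normal tissue for each of these 3 genes. The NK and cytotoxic (8 of 8, median -2.20), macrophage and monocyte (10 of 15, median -0.92), stroma and endothelium (14 of 15, median -1.57) and adipocyte lists (4 of 4, median -2.71) also fell. Mature B cell genes fell in 10 of 12 cases (median -1.81, where Fcer2a, the low-affinity IgE receptor, fell by 4.47 ± 0.28). Germinal centre genes fell in 6 of 7 (median -1.97, where Bcl6 fell by 2.93 ± 0.13), and plasma cell genes in 10 of 13, with 1 higher (median -1.35, where Jchain, which joins secreted antibody, fell by 4.45 ± 0.51). All 14 NF-kB targets (median -2.37, where Cd83 fell by 3.79 ± 0.18, Relb fell by 3.26 ± 0.26) and all 13 interferon response genes (median -1.93, where Irf7 fell by 2.56 ± 0.23) were lower. All 9 MHC class II genes (median -1.87, where H2-Oa fell by 2.39 ± 0.14) and all 9 MHC class I genes (median -0.96, where Tapbp fell by 1.69 ± 0.10) were lower. So were 11 of 12 immediate early and heat shock genes (median -1.54, where Egr1 fell by 1.96 ± 0.48) and 7 of 9 JAK-STAT feedback genes, with 1 higher (median -1.10, where Socs3 fell by 2.65 ± 0.24). These 14 lists were called down, with adjusted p between 1.7e-06 and 0.045. Adjusted over the list alone, 11 mature B genes were lower and 2 plasma cell genes were higher, and the other 12 counts were as above. None of the 14 was called with an estimated correlation (adjusted p from 0.10 to 0.36).

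The other lists were not called between early lymphoma and normal tissue. Immunoglobulin genes fell in 3 of 4 cases (median -4.54, list adjusted p = 0.063). The p53 targets fell in 8 of 13 cases with 1 higher (median -0.63, p = 0.19) and Ras and ERK feedback genes in 4 of 11 (2 adjusted over the list alone, median -0.73, p = 0.48). The B lineage list had 3 members higher and 2 lower (2 and 2 adjusted over the list alone, median -0.02, mean 0.06 and a list test pointing up at adjusted p = 0.66, and the median became 0.32 after centring on the median). The pro-B and pre-B list had 4 higher and 4 lower. Rag1, of antigen receptor rearrangement, rose by 3.08 ± 0.82, Myb rose by 2.79 ± 0.11 and the cytokine receptor gene Il7r fell by 2.83 ± 0.38. Platelet genes fell in 2 of 4 cases, and Wnt targets were split 3 higher and 3 lower. Glycolysis and hypoxia genes had 6 higher and 5 lower (6 and 6 adjusted over the list alone, median -0.23 and mean -0.03 with a list test pointing up at adjusted p = 0.48, and the median became 0.11 after centring). Neutrophil genes (median 0.12, mean -0.02) and sex-linked genes (median -0.05, which became 0.29 after centring) had 0 called, with list tests pointing up at adjusted p = 0.96 for both. In the Arf, p53 and Bcl2 family 3 rose and 7 fell (median -0.25, which became 0.09 after centring). Bcl2 fell by 1.82 ± 0.17, and the change of Cdkn2a, which encodes Arf and p16, was 0.91 ± 0.45 (adjusted p = 0.071, and 0.041 with the RNA ratios as covariates). Mdm2 fell by 0.50 ± 0.16, and Ighm changed by -0.14 ± 0.15 (adjusted p = 0.43).

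Over all probe sets, 18460 of 27094 passed the threshold, 7687 higher and 10773 lower in early lymphoma, and 6835 of them changed at least 2-fold. The share of higher calls was 41.6%, and it became 54.8% after quantile normalization and 65.1% after centring on the median, with the median of all probe sets moving from -0.12 to 0.08 and 0.22. Normal arrays had the higher median intensity, and the directions of the called lists above were unchanged by either scaling.

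Late lymphomas, too, differed from normal tissue in genes of proliferation, growth and the immune compartment. All 19 mitotic genes (median 2.02, with Ube2c 2.57 ± 0.23), 20 of 21 E2F targets (21 adjusted over the list alone, median 1.51) and 10 of 11 DNA repair genes (median 1.08) were higher. So were all 18 ribosome biogenesis genes (median 1.70, with Nolc1 2.44 ± 0.18), all 15 Myc metabolic targets (median 1.67, with Nme1 2.56 ± 0.16), 14 of 15 oxidative phosphorylation genes (median 0.59) and 4 of 9 ribosomal protein genes (median 0.17). All 15 T cell genes (median -2.67, where Cd3d fell by 5.09 ± 0.72), 7 of 8 NK and cytotoxic genes (median -1.67) and 11 of 12 mature B genes (12 adjusted over the list alone, median -2.24, where Fcer2a fell by 4.25 ± 0.25) were lower. So were 12 of 15 stroma and endothelium genes (median -1.37), all 4 adipocyte genes (median -2.83) and all 14 NF-kB targets (median -1.56). Lower as well were 11 of 13 interferon response genes (median -1.68), all 9 MHC class II genes (median -1.42), 8 of 9 MHC class I genes (median -0.75), 9 of 11 Ras and ERK feedback genes (median -0.85, where Dusp6 fell by 1.76 ± 0.35) and 9 of 12 immediate early genes (median -0.98). Where no other count is given, adjustment over the list alone gave the same count. These 18 lists were called at adjusted p up to 0.024, and 0 were called with an estimated correlation (adjusted p from 0.12 to 0.46).

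The largest rises in late lymphoma were Cenpi (3.41 ± 0.31), Myc, Lingo3 (2.93 ± 0.49), Acy1 (2.89 ± 0.29), the cohesion factor Cdca5 (2.86 ± 0.19), Gm10451 (2.84 ± 0.51), Padi4 (2.82 ± 0.40), Bcat1 (2.70 ± 0.54), Dyrk3 (2.68 ± 0.35) and the replication gene Ticrr (2.65 ± 0.21). The largest falls were Glycam1, an endothelial ligand of lymph node venules, which fell by 6.92 ± 0.70, Cd3d and Dapl1 (fell by 4.94 ± 0.32). They also included Prkcq, a kinase of T cell receptor signalling (fell by 4.85 ± 0.46), Ltb, Marco (fell by 4.43 ± 0.59), Ms4a4b, Trbv1, Satb1 (fell by 4.30 ± 0.50) and Fcer2a. Early lymphomas also had Cd3d, Marco (fell by 5.70 ± 0.52), Glycam1 (fell by 5.38 ± 0.76), Ms4a4b, Prkcq, Ltb, Dapl1 and Trbv1 among their 10 largest falls, beside Ighg3 (fell by 5.31 ± 0.35) and Iglv1 (fell by 5.11 ± 0.68). Cdkn2a rose by 1.47 ± 0.53 in late lymphomas (adjusted p = 0.018), with 14 of 25 above every normal tissue. Plasma cell genes had 1 higher and 1 lower member (median -0.20, mean -0.18 and a list test pointing up at adjusted p = 0.96, and the median became 0.08 after centring).

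In late lymphoma against normal tissue 14849 probe sets passed the threshold, 6072 higher and 8777 lower, and 5249 changed at least 2-fold. The share of higher calls was 40.9%, against 55.3% after quantile normalization and 65.8% after centring, and the median of all probe sets moved from -0.09 to 0.08 and 0.19. Against the 4 old normal tissues alone 9785 probe sets passed, and 19 named genes then lost their call, among them Cdkn2a (1.42, adjusted p = 0.19).

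The comparisons of early and late lymphoma with normal tissue share their 10 control arrays. Their log2 changes correlated at 0.94 across the kept probe sets, which are not independent replicates, against 0.53 in simulations of unchanged groups. The covariance was 0.81 against a simulated 0.015. Of the called probe sets 5557 were higher in both and 8128 lower in both, where independent lists would give 1723 and 3490, and 3 were called in opposite directions. With the controls split between the comparisons the correlation was 0.90 and the covariance 0.79, averaged over 20 draws.

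**Figure D2:**
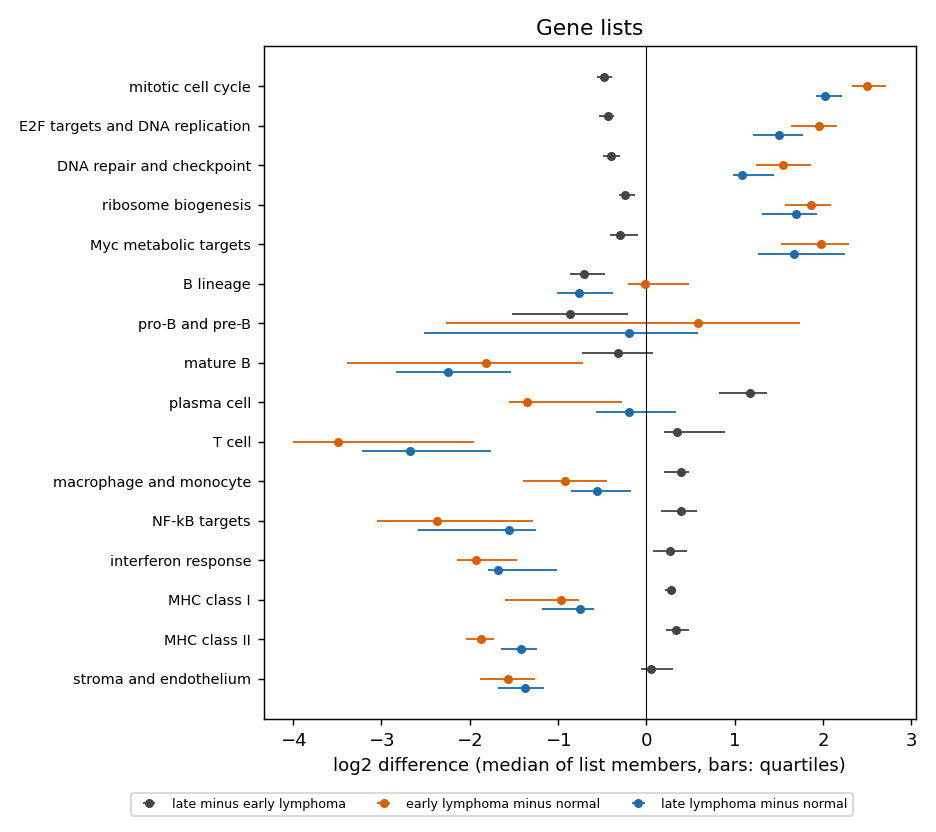
Median log2 difference of the members of 16 gene lists for late minus early lymphoma, early lymphoma minus normal tissue and late lymphoma minus normal tissue; bars span the quartiles of the members. Mitotic cell cycle genes lie at 2.50 in early and 2.02 in late lymphomas against normal tissue, and plasma cell genes at 1.17 in late against early lymphomas.

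Between late and early lymphomas most mitotic and DNA repair genes, and 4 of 9 pro-B and pre-B genes, were lower in the late ones, and most plasma cell genes were higher. None of these lists was called with an estimated correlation (adjusted p = 0.38 for each). Of 19 mitotic genes 18 were lower in late lymphomas, with a median change of -0.48. Cdk1 fell by 0.70 ± 0.15, Bub1 by 0.66 ± 0.15 and Plk1 by 0.65 ± 0.14, and Cdk1 lay below every early lymphoma in 17 of the 25 late ones. E2F targets fell in 13 of 21 cases (16 adjusted over the list alone, median -0.44, where Pola1 of the replicative polymerase fell by 0.71 ± 0.17), and DNA repair and checkpoint genes fell in 10 of 11 (11 adjusted over the list alone, median -0.40). Myc metabolic targets fell in 7 of 15 (9 adjusted over the list alone, median -0.30, where Shmt1 fell by 0.84 ± 0.13). Ribosome biogenesis genes fell in 6 of 18 (9 adjusted over the list alone, median -0.24, where Nop58 fell by 0.41 ± 0.12) and oxidative phosphorylation genes in 4 of 15 (5 adjusted over the list alone, median -0.11, where Ndufa9 fell by 0.27 ± 0.06). Plasma cell genes rose in 10 of 13 cases (11 adjusted over the list alone, median 1.17, with Jchain 2.15 ± 0.54, Ell2, an elongation factor of antibody secretion, 1.83 ± 0.47, Creld2 1.44 ± 0.31), and Jchain lay above every early lymphoma in 11 of the 25 late ones. The late lymphomas spread widely in these lists. The mean level of the plasma cell list was 10.8 ± 1.36 in late and 9.68 ± 0.27 in early lymphomas (SD), while the medians were 10.3 and 9.63, and 15 late lymphomas lay above every early one and 2 below. Late lymphomas 120, 125, 129, 137 and 138 had the highest levels of this list (12.9 to 13.5), and their levels of the mitotic list were 10.7, 10.9, 10.7, 9.41 and 10.8. Their Gapdh 3-prime to 5-prime log2 ratios were -0.52, -0.48, -0.55, -0.51 and -0.61, and those of 120, 129, 137 and 138 were the 4 lowest among the 50 lymphomas. The mean of the mitotic list was 11.3 ± 0.54 in late and 11.7 ± 0.14 in early lymphomas, with medians of 11.4 and 11.7.

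The B lineage list fell in 5 of 11 cases (8 adjusted over the list alone, median -0.70, where Cd79a of the B cell receptor fell by 1.65 ± 0.49, the transcription factor Ebf1 by 1.55 ± 0.33 and Pax5 by 0.64 ± 0.17). The mean level of the B lineage list was 11.0 ± 1.03 in late and 11.7 ± 0.49 in early lymphomas (SD), with medians of 11.4 and 11.9. It was lowest in late lymphomas 130, 131, 117, 133 and 127, at 8.65 to 9.81, and was 9.56 in early lymphoma 6. The pro-B and pre-B list fell in 4 of 9 (median -0.87, where Rag1 fell by 2.16 ± 0.65, Sox4 by 1.66 ± 0.38, Cd93 by 1.52 ± 0.30 and Myb by 1.45 ± 0.32). Higher in late lymphomas were 6 of 14 NF-kB targets (8 adjusted over the list alone, median 0.39, with Bcl3 1.25 ± 0.26, Ebi3 1.27 ± 0.34, Cd83 1.19 ± 0.24) and 3 of 12 immediate early genes (5 adjusted over the list alone, median 0.42, with Fos 0.93 ± 0.20). So were 2 of 7 germinal centre genes (median 0.54, with Bcl6 0.54 ± 0.16) and 3 of 9 MHC class I genes (median 0.28, with Tapbp 0.51 ± 0.13). Higher as well were 3 of 13 interferon response genes (median 0.27, with Bst2 1.51 ± 0.31) and 2 of 13 p53 targets with 1 lower (median 0.30, with Sesn2 0.94 ± 0.21). Also higher were 5 of 15 T cell genes (median 0.34, with Cd8b1 2.04 ± 0.53, Cd28 1.04 ± 0.34, Thy1 0.99 ± 0.27). The same held for 6 of 15 macrophage and monocyte genes (7 adjusted over the list alone, median 0.39, with Mpeg1 0.85 ± 0.25). It held for 1 of 8 NK and cytotoxic genes (median 0.58, with Klrk1 0.84 ± 0.29). These 18 lists were called with the preset correlation at adjusted p from 2e-10 to 0.038, and 0 were called with an estimated correlation (adjusted p from 0.38 to 0.54). Late lymphomas 117, 131 and 133 had Cd8b1 at 13.4, 13.6 and 13.9 with Cd3d at 7.80, 5.80 and 5.03. Late lymphoma 130 had Cd8b1 at 12.8 and Cd3d at 13.3. Cd8b1 thus need not come from T cells in every tumour.

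Lists not called between late and early lymphoma were mature B (1 higher, 2 lower of 12), immunoglobulin (2 higher of 4; Ighg3 1.09 ± 0.41), stroma and endothelium (1 higher of 15; Mgp 1.27 ± 0.28), platelet (1 higher of 4), MHC class II (0 of 9 called), adipocyte (0 of 4) and neutrophil (0 of 8). Ribosomal proteins (0 of 9), Ras and ERK feedback (1 lower of 11) and Wnt targets (3 lower of 10, of which Tnfrsf19 fell by 1.38 ± 0.43) were not called either. The same held for JAK-STAT feedback (2 higher of 9, 3 adjusted over the list alone; the survival kinase Pim1 0.77 ± 0.17), glycolysis and hypoxia (2 higher, 1 lower of 15) and the Arf, p53 and Bcl2 family (2 higher, 1 lower of 15; Mcl1 0.30 ± 0.08). In that family Cdkn2a changed by 0.56 ± 0.44 (adjusted p = 0.37) and Bcl2 by 0.51 ± 0.32 (adjusted p = 0.25). Mdm2 changed by 0.17 ± 0.13 (adjusted p = 0.37). Ighm changed by -0.74 ± 0.36 (adjusted p = 0.13), and 3 other probe sets of Ighm were called in the opposite direction.

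The largest rises in late lymphomas were the surface antigen genes Ly6k (2.56 ± 0.58) and Ly6d (2.31 ± 0.50), Jchain, Cd8b1, Slc2a6 (2.00 ± 0.40), Ctsw (1.90 ± 0.41), Serpini1 (1.88 ± 0.36), Ell2, Klra17 (1.76 ± 0.50) and Cyp2b10 (1.72 ± 0.56). The largest falls were Tmem255a (fell by 2.69 ± 0.57), 4921525O09Rik (fell by 2.38 ± 0.47), Xist (fell by 2.20 ± 0.73), Ptgr1 (fell by 2.19 ± 0.36) and Rag1. Next came Akap12 (fell by 2.03 ± 0.34), Vpreb3 (fell by 2.02 ± 0.48), Trib2 (fell by 1.88 ± 0.38), Bcat1 (fell by 1.86 ± 0.34) and Otub2 (fell by 1.86 ± 0.38). Xist, of the inactive X chromosome, lay above the midpoint of its range in 17 early and 7 late lymphomas, and the Y-linked Eif2s3y in 8 and 18 (Fisher's exact p = 0.010 for each). The other Y-linked genes put to this test did not pass, with Kdm5d above its midpoint in 13 early and 19 late lymphomas (p = 0.14) and Uty in 12 and 19 (p = 0.079). Among the 10 normal tissues 8 lay above the midpoint for Xist, 2 for Eif2s3y, 5 for Kdm5d and 7 for Uty. The midpoints of Kdm5d and Uty thus do not split the arrays as those of Xist and Eif2s3y do. Their results cannot count against a difference in sex between the groups. The labels do not give sex, which by Xist and Eif2s3y may differ between early and late lymphomas. In the sex-linked list, which was not called (1 higher and 1 lower of 4, with 2 higher and 1 lower adjusted over the list alone), Uty rose by 0.78 ± 0.28. With the level of Eif2s3y as a covariate 6237 probe sets were called.

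Over all probe sets 5951 of 27094 differed between late and early lymphomas, 2596 higher and 3355 lower, and 478 of them by at least 2-fold, 317 higher and 161 lower. The share of higher calls was 43.6% over all calls and 66.3% over those of at least 2-fold, and over all calls it was 31.5% after centring on the median. The Gapdh 3-prime to 5-prime log2 ratio was -0.38 ± 0.05 in early and -0.43 ± 0.07 in late lymphomas (SD, n = 25 each; permutation test, adjusted p = 0.030), and the other 5 quality measures did not pass. With the Gapdh and actin ratios as covariates 1745 probe sets were called, 1687 of them also called without. The members called then fell to 5 of 19 in the mitotic list (median -0.32), 3 of 21 E2F targets (median -0.30), 4 of 11 DNA repair genes (median -0.35), 2 of 15 Myc metabolic targets (median -0.16), 0 of 18 ribosome biogenesis genes (median -0.16) and 2 of 13 plasma cell genes (median 0.68). In that fit 2 of 11 B lineage (median -0.67) and 3 of 9 pro-B and pre-B genes (median -1.02) were called. With the levels of the T cell, macrophage and stroma lists as covariates 1007 were called, among them 3 mitotic genes (median -0.29) and 1 plasma cell gene (median 0.72). In that fit 0 NF-kB targets, 0 MHC class I genes (median -0.02) and 1 interferon response gene (median -0.23) were called, and the medians of the MHC class I and interferon lists thus turned direction. With the RNA ratios 50 named genes lost their call, among them Cd79a (adjusted p = 0.076), Rag1 (0.053) and Ell2 (0.10). With the cell type lists 76 named genes lost it.

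**Figure D3:**
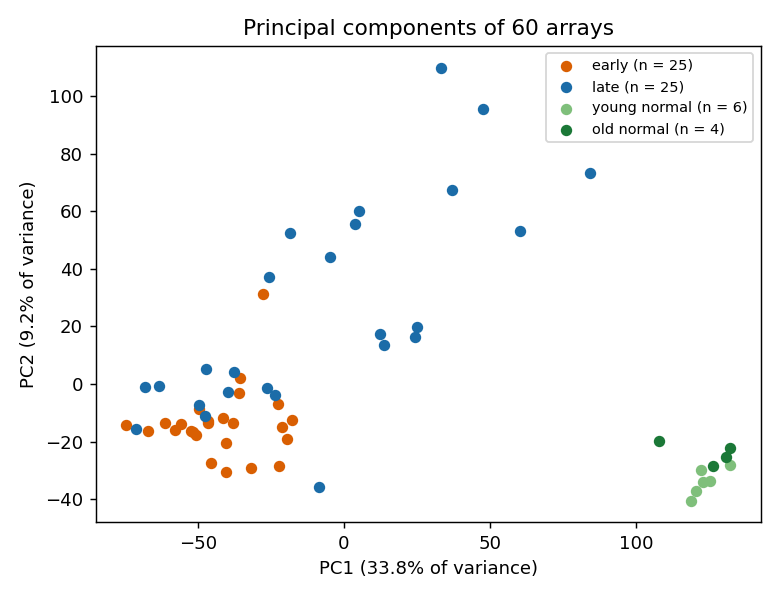
The first 2 principal components of the 60 arrays over the kept probe sets, as scores, with early and late lymphomas and young and old normal tissue in colours. Normal tissues lie apart along component 1, which carries 33.8% of the variance, and late lymphomas scatter more widely than early ones.

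Late lymphomas were more heterogeneous than early ones. The mean distance of an array to its group mean was 106 ± 16.4 for late and 81.1 ± 14.3 for early lymphomas (SD, n = 25 each), a difference of 24.7 (two-sided permutation test, p = 3e-05), and 4 late lymphomas lay further out than every early one. The first principal component carried 33.8% of the variance and separated normal tissue (mean score 124 ± 7.4) from early (-42.2 ± 15.3) and late lymphomas (-7.4 ± 41.7). The second carried 9.2%.

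In normal tissue, plasma cell and antibody genes were higher in old than in young mice. Of 13 plasma cell genes 11 were higher in old tissue (12 adjusted over the list alone, median 1.13, with list adjusted p = 1.7e-21, and 0.042 with an estimated correlation) and all 4 measured immunoglobulin genes rose (median 0.78, with adjusted p = 6.7e-09, and 0.0071 with an estimated correlation). The largest rises included the light chain genes Igkv6-14 (2.88 ± 0.25) and Igkv6-20 (2.49 ± 0.39), the protease inhibitor gene Slpi (2.69 ± 0.32) and Ighg3 (2.39 ± 0.14). Stroma and endothelium genes fell in 5 of 15 cases (median -0.63), and the collagen gene Col3a1 fell by 2.11 ± 0.31. The malic enzyme gene Me1 fell by 2.25 ± 0.45, Acaca of fatty acid synthesis by 1.67 ± 0.36, Dusp18 by 1.48 ± 0.28 and Itgb4 by 1.41 ± 0.24. The stroma list (9 lower and 1 higher adjusted over the list alone) was called at adjusted p = 8.3e-08 and not with an estimated correlation (adjusted p = 0.27). MHC class I genes had 0 of 9 past the threshold over all genes and 6 higher adjusted over the list alone (median 0.28, with list adjusted p = 3.1e-05, and 0.49 with an estimated correlation). The adipocyte list had 0 of 4 genes past the threshold, also adjusted over the list alone (median -1.59, with list adjusted p = 0.022, and 0.49 with an estimated correlation), and its mean level was 7.83 in the spleen and at least 11.6 in every lymph node. The list test also called B lineage, macrophage and monocyte, ribosomal protein and MHC class II genes upward and pro-B and pre-B, ribosome biogenesis, Ras and ERK feedback and oxidative phosphorylation genes downward (adjusted p from 0.00022 to 0.039), none of them with an estimated correlation (adjusted p from 0.11 to 0.66). The level of the macrophage and monocyte list was 11.4 in the spleen and at most 11.0 in the lymph nodes.

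Over all probe sets 374 passed between old (n = 4) and young (n = 6) normal tissue, 220 higher and 154 lower. The old tissues had a Gapdh ratio of -0.32 ± 0.02 against -0.43 ± 0.05 in young ones, and with both RNA ratios as covariates 3 probe sets were called. Of the genes named for this comparison 9 then lost their call, among them Igkv6-14 (adjusted p = 0.050). The 3 calls were all rises, so none of the named falls kept its call. In that fit 0 of 13 plasma cell genes (median 1.12), 1 of 4 immunoglobulin genes and 0 of 15 stroma genes were called. Leaving out old lymph node 8 gave 232 calls and leaving out old lymph node 10 gave 241. Sex, which the labels do not give, may also differ between old and young tissue. Xist was 14.1 to 14.2 in all old tissues. In young lymph nodes 1 and 4 it was 8.02 and 8.70, with Eif2s3y at 10.3 and 10.5, and in the other young nodes Xist was at least 13.9. The comparison was not adjusted for sex.

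The onset difference in lymphomas was tested against the age difference in normal tissue with an interaction over the 60 samples. It called 7 probe sets, all with a more positive change in lymphomas. Their genes by the naming rule were Thrsp (2.13 ± 0.45), Fasn (1.70 ± 0.32), Dgat2 (1.62 ± 0.32) and Acaca (1.41 ± 0.29), which act in the synthesis of fatty acids and fat. In normal tissue Acaca fell with age, and the old minus young changes of Thrsp (-2.01 ± 0.61), Fasn (-1.68 ± 0.48) and Dgat2 (-1.46 ± 0.42) did not pass the threshold. In lymphomas Acaca fell by 0.27 ± 0.10, and the late minus early changes of Thrsp, Fasn and Dgat2 were 0.12, 0.02 and 0.16 and did not pass. The adipocyte list, lowest in the spleen, was called upward in the interaction (median 1.77, 0 of 4 genes past the threshold and 2 adjusted over the list alone, with list adjusted p = 0.00078, and 0.48 with an estimated correlation). Also called upward were the stroma and endothelium (median 0.90, adjusted p = 1.5e-06), T cell (0.75, p = 0.019) and NF-kB lists (0.28, p = 0.014). Called downward were the mitotic (median -0.48, adjusted p = 1.5e-06), E2F (-0.50, p = 1.5e-06), B lineage (-0.87, p = 0.00022), DNA repair (-0.26, p = 0.0037), Myc metabolic (-0.37, p = 0.0039) and neutrophil lists (-1.33, p = 0.031), the last of which had a level of 12.3 in the spleen and at most 9.90 in the lymph nodes. No member of these 9 lists passed the threshold, adjusted over the list alone 2 stroma genes did, and none of the lists was called with an estimated correlation (adjusted p from 0.48 to 0.66). The plasma cell list was not called (median 0.01, mean -0.02 and a list test pointing down at adjusted p = 0.69). Nor was the sex-linked list (median 1.30, list adjusted p = 0.19), of which 2 genes were higher and 1 lower adjusted over the list alone. High Xist was rarer in late than in early lymphomas but was found in all old normal tissues. Sex may thus weigh on the interaction, which was not adjusted for it. Without the spleen, the count of probe sets was 1 and none of Thrsp, Fasn, Dgat2 and Acaca passed. It was 2 without old lymph node 10, 15 without old lymph node 8, 3 with the RNA ratios, 1 after centring, 11 after quantile normalization and 617 with array weights.

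Age of onset within a group was tested on the log2 scale. Within late lymphomas (n = 25) 3 probe sets fell with age. They were 2 of the chromatin remodelling gene Smarca4, whose representative fell by 1.15 ± 0.18 per doubling of age, and 1 of the RNA polymerase gene Polr2a, which fell by 0.99 ± 0.16. An unadjusted p under 0.05 was reached by 5839. The count was 0 with the RNA ratios, 2160 with array weights, 378 without late lymphoma 120, 96 without late lymphoma 141, and 0 when late lymphoma 112, 113, 137 or 138 was left out singly. It was 6 without late lymphoma 111 or 123 and 5 without 124. Within early lymphomas (n = 25) 2434 followed age, 542 rising and 1892 falling. The largest were Gadd45b (2.60 ± 0.67, with 1 other probe set opposite), Adssl1 (2.32 ± 0.53), Gga1 (1.80 ± 0.28), Armc5 (1.78 ± 0.27) and Cep83os (1.75 ± 0.50) upward. Downward they were Irs1 (fell by 3.00 ± 0.88), Adgrg3 (fell by 1.95 ± 0.45), the chemokine gene Ccl2 (fell by 1.79 ± 0.43), 0610040F04Rik (fell by 1.75 ± 0.37) and Kctd15 (fell by 1.68 ± 0.43). Without early lymphomas 1 and 2, the youngest at 32 and 42 days, 7 probe sets were called and none of these 10 genes passed. The count was 552 without early lymphoma 1 alone and 840 without early lymphoma 2 alone. The share of rising calls was 22.3%, against 59.6% after quantile normalization and 94.4% after centring, with the median slope of all probe sets moving from -0.09 to 0.03 and 0.34. In late lymphomas that median moved from 0.04 to -0.05 and -0.14.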

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

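The tests of normal tissue share, of T cells and of early lymphomas 1 and 2 were chosen only after the results were seen. The same holds for the 10th percentile of intensity as a covariate and for the test of plasmacytoid dendritic cell markers. These markers were not among the lists fixed before the data were examined. In groups of 4 to 10 normal tissues 171 sets of values were searched for a sample far from the others, and 15 were found, where chance gives about 5%.

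Normal spleen 7 stood apart from the 9 lymph nodes in mean log2 levels of the T cell list (10.155, nearest 10.761), the macrophage and monocyte list (11.438, nearest 11.002), the neutrophil list (12.261, nearest 9.9001), the platelet list (10.914, nearest 9.0044), the adipocyte list (7.8296, nearest 11.645) and Cdkn2a (6.0517, nearest 6.8677). Among the 4 old tissues it stood apart in the platelet list (nearest 8.8237), the adipocyte list (nearest 11.804), the glycolysis and hypoxia list (10.129, nearest 10.401), Cdkn2a (nearest 7.387) and Bcl6 (10.356, nearest 10.024). Lymph node 8 was lowest in the Arf, p53 and Bcl2 family (9.9181, nearest 9.9883) and, among old tissues, highest in the plasma cell list (12.017, nearest 11.506). Among old tissues, lymph node 9 had the highest 10th percentile of intensity (16.48, nearest 14.83) and lymph node 10 the highest oxidative phosphorylation list (12.145, nearest 12.074).

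The late minus early change in lymphomas differed from the old minus young change in normal tissue, by limma's interaction test, for an unnamed probe set (4.2169), Thrsp (2.1328), Gtf2i (2.0539), Fasn (1.7037), Dgat2 (1.6199), Pdk1 (1.5833) and Acaca (1.4086). Gtf2i and Pdk1, by probe sets that do not represent their genes here, were named after their values were seen. The 7 probe sets were matched or exceeded by 2 of 100 groupings of the arrays, the real one included, and the highest other grouping gave 11. These groupings shuffled onset among lymphomas and age among normal tissues. They thus stand for no difference of either kind, and not for equal differences.

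The count of 5951 probe sets between early and late lymphomas was reached by 1 of 100 groupings, the real one, and the highest other gave 390. For early lymphoma against normal tissue the real 18460 was reached by 1 of 100 with 6402 as the highest other, for late lymphoma against normal 14849 by 1 of 100 with 5, and for old against young normal tissue 374 by 1 of 100 with 54. For age within late lymphomas the real 3 was reached by 2 of 100 with 5 as the highest other, and for age within early lymphomas 2434 by 1 of 100 with 232. For the 5 counts that no other grouping reached, chance is improbable at 1 of 100. That is the lowest share 100 groupings can give, so chance is not excluded. For the 7 of the interaction and the 3 of age within late lymphomas 1 other grouping each gave more, so chance can give such counts. For age within late lymphomas chance is improbable at 2 of 100. For the interaction the groupings held neither difference, so 2 of 100 does not measure chance under equal differences.

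Mitotic genes were lower in late than in early lymphomas, with a median log2 change of -0.48. A larger share of normal tissue would need 29.3% of it. Of 617 genes at least 4-fold higher in normal tissue than in early lymphomas 499 stayed below the level this brings (median log2 ratio of all of them -0.65, upper 95% bootstrap bound -0.42712). This argues against normal tissue of the composition measured here as the whole cause. The genes were picked on the same arrays, which can push the ratio down, and normal cells of another composition were not tested. Scaling left the median at -0.45913 after quantile normalization. With the 3-prime to 5-prime ratios as covariates it was -0.32243 (median SE 0.12 before and after) and 5 rather than 18 of 19 genes passed. The changes shrank while their errors did not, and with 1745 rather than 5951 calls in all the adjustment was also stricter. These effects were not separated. The ratios may account for part of the fall. Whether they account for all of it stays open, since the list test was not run with the ratios as covariates. In normal tissue 0 of 19 mitotic genes passed between old and young (median -0.015, list adjusted p = 0.87). The interaction called the list downward (median -0.48, list adjusted p = 1.5e-06), but not with an estimated correlation (adjusted p = 0.62). Normal tissue cannot show what age does in lymphomas. Age, the kind of tumour and, by Xist and Eif2s3y, perhaps sex differ with onset in this design and stay open. The kind of tumour was not tested.

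The number of probe sets that follow age within early lymphomas was 2434, and 7 with early lymphomas 1 and 2 left out. These arrays have the highest low-end intensities (10th percentiles of 28.1 and 21.1). Their Bacillus controls were 5.70 and 4.96, against a mean of 3.58 ± 0.66 (SD) in early lymphomas. Their array medians were 206 and 205, against 148 ± 19.5 (SD). The Bacillus controls are not mouse genes, so the age of a mouse does not account for their levels. With the 10th percentile of intensity as a covariate the number of probe sets that follow age was 1. Brightness of the low end of these arrays is thus a candidate explanation, and since these 2 lymphomas also have the youngest onset, an effect of age stays open.

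Cd8b1 (2.04 ± 0.53) and Cd7 (1.88 ± 0.62, chosen after its values were seen) had higher means in late than in early lymphomas. For Cd7 a few arrays carry this, since the medians were 5.71 in late and 5.38 in early lymphomas with an SD of 3.19 and 0.25, and 8 of 25 late lymphomas lay above every early one. For Cd8b1 the medians were 8.92 and 6.83, and 13 late lymphomas lay above every early one. The upper quartile of the change of 12 other T cell markers was 0.86507, below the change of Cd8b1 by more than 2 of its standard errors. Cd8b1 was itself named as one of the largest rises, so this comparison cannot decide whether T cells are its whole source. In single tumours, late lymphomas 117, 131 and 133 had high Cd8b1 with low Cd3d, and late lymphoma 130 had both high. Of 11 measured markers of plasmacytoid dendritic cells 6 were higher and 0 lower (median 0.79), with Siglech at 1.54, Bst2 at 1.51, Sla2 at 1.12, Cox6a2 at 1.10, Tcf4 at 0.79 and Lair1 at 0.74, so such cells, or tumour cells with these transcripts, may contribute. The list test of these markers, chosen after the results were seen, gave p = 2.3e-05, and p = 0.064 with an estimated correlation. Bst2 also stands in the interferon list, and all 11 had a mean above the table median in normal lymphoid tissue. Age and the kind of tumour stay open, and the kind of tumour was not tested.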

How the results depend on the processing

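Early lymphomas 1 and 2 left out, the 10th percentile and Eif2s3y covariates and leaving out lymphomas singly were tests chosen after the data were seen. Of the list results 496 kept direction and side of the threshold, 53 lost the call, 16 gained it and 11 reversed; of the named genes 5302, 427, 7 and 5 did. The difference in spread kept its direction and call in all 5 alternatives (0.029552 as 1 minus correlation, 12.864 over the most variable probe sets, 25.397, 23.464 and 23.579). The cause of the changes below was not tested, except where fewer samples or genes, or a stricter criterion, entered by construction. For early against late lymphoma the handling of dim probe sets kept the count between 5461 (stricter filter) and 6045 (a pseudocount 4 times larger).

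For early against late lymphoma the count was 1745 with RNA quality covariates, 478 at 2-fold or more, 1007 with cell type list covariates, 3078 with 1 probe set per gene, which tests fewer, and 5022 (without late lymphoma 137) to 6754 (without 112) with lymphomas left out singly. It was 6835 at 2-fold for early lymphoma against normal and 5249 for late lymphoma against normal, where 4 old normal tissues only gave 9785 and leaving out each of them gave 8102 (spleen 7), 7683 (lymph node 8), 7841 (node 9) and 7783 (node 10). Old against young tissue gave 3 with RNA quality covariates and 232 (without lymph node 8) to 386 (without spleen 7), with 241 without node 10.

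The interaction gave 33 with no filter, 4 with the stricter filter, 11 after quantile normalization, 1 after centring, 3 with RNA quality covariates, 617 with array weights, 1 with the spleen left out, 12 without early lymphomas 1 and 2, and 1 (without spleen 7) to 15 (without lymph node 8), with 2 without node 10. Age within late lymphomas gave 6 with the stricter filter, 6 after quantile normalization, 7 after centring, 0 by limma with RNA quality covariates (3172 at an unadjusted p under 0.05), 2160 with array weights, and 0 (without 112, 113, 137 or 138) to 378 (without 120), with 96 without 141, 6 without 111 or 123 and 5 without 124. Age within early lymphomas gave 5138 with no filter, 1563 after quantile normalization, 7743 after centring, 706 with array weights, 7 without early lymphomas 1 and 2, 1 with the 10th percentile as a covariate, and 552 (without 1) to 3071 (without 6), with 840 without 2. Of 56 list shifts 5 were called with an estimated correlation.

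Log2 changes that reversed were those of Ighm, early - normal, after centring (0.2009) and against 6 young lymph nodes (0.14702), Lcn2, early - normal, against the young nodes (0.074958) and with the replicate block (0.15925), and Myc, late - early, with cell type covariates (0.013421). List tests also reversed, given here by adjusted p. After quantile normalization these were list B lineage, early - normal (0.90834), and list pro-B and pre-B, early - normal, list neutrophil, early - normal, and list sex-linked, early - normal (0.9674 each). After centring they were list pro-B and pre-B and list neutrophil (0.70497 each), list Wnt and beta-catenin targets, early - normal (0.99457), and list sex-linked (0.70596). The list plasma cell, late - normal, reversed after quantile normalization (0.62146), after centring (0.58731) and with cross-hybridising probe sets left out (0.92437).

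With the sample number as a replicate block, early lymphoma against normal gave 16252 calls. The 9 pairs of shared numbers are different mice, with correlations of deviations from -0.109 to 0.084 and 0 of 9 best matched to their own number. No likeness by number was thus seen, which cannot show whether a litter, a day or a batch was shared.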

Other observations

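No test was run in this part. The arrays below were chosen after their values were seen, and their log2 levels are given singly, with no comparison. Late lymphomas 120, 125, 129, 137 and 138 had Jchain, of secreted antibody, at 14.8, 14.8, 14.8, 14.7 and 14.7, the plasma cell surface gene Sdc1 at 12.7, 11.4, 12.4, 13.1 and 12.5, and the secretory regulator Xbp1 at 15.0, 14.7, 14.7, 14.5 and 14.6. Their levels of the B cell receptor gene Cd79a were 10.5, 9.12, 12.0, 10.5 and 7.52.

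Late lymphomas 116, 117, 127, 131 and 133 had Cd7 at 12.4, 13.1, 13.6, 13.5 and 13.7, Cd4 at 11.9, 12.7, 12.4, 12.7 and 13.4, and Cd8b1 at 11.1, 13.4, 9.05, 13.6 and 13.9, with Cd3d of the T cell receptor complex at 4.90, 7.80, 5.01, 5.80 and 5.03. Late lymphoma 130 had Cd3d at 13.3, Lat at 12.6, Cd8b1 at 12.8 and Cd79a at 9.06. Early lymphoma 6 had Cd79a at 7.01, late lymphoma 114 had Ighm at 6.98 and late lymphoma 113 had Rag1 at 12.3.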
